A study of Mus musculus with 31 samples.

How the data were processed

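RNA of LT-HSCs was sequenced in 31 libraries, 4 for each of 8 groups (2 genotypes by 4 treatments) except VFDM COMBO with 3. The deposited table holds raw gene counts made by the authors, per the labels with reads aligned to mm10, for 55492 rows, of which 55141 have a gene symbol and 5 are transgene rows. The submitters' processing notes name FastQC 0.11.5, STAR 2.7.10a, featureCounts and R 4.3.0. The annotation, the strand setting and the handling of reads with several mapping positions are not given in the sources used here, so antisense, overlapping and near-identical genes are uncertain. Gene symbols, positions and classes were taken from GENCODE vM21.

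Counts were analysed in R 4.3.3 with edgeR 4.0.16. TMM factors were computed on all 31 libraries, rows were kept with filterByExpr (at least 10 reads in enough libraries and 15 in total, 22172 rows), and a quasi-likelihood model with robust dispersions and 1 mean per group was fitted. Genes with a Benjamini-Hochberg adjusted p under 0.05 over the 22172 rows were called, in 17 planned comparisons and 3 added after the data were seen. These were 6 treatments against the vehicle of the same genotype, 2 genotype comparisons (vehicle, and the average over 4 treatments), 4 of COMBO against a drug alone, 3 differences of a response between genotypes (interaction terms) and 2 non-additivity terms, the latter testing COMBO against the sum of the drugs on the log scale. All tests were two-sided. The SE of a log2 fold change is its size divided by the square root of the quasi-likelihood F. CPM are per TMM-scaled library. The p-values measure the spread between these libraries, and the labels do not say that each came from a separate animal. Comparisons that share a control group are not independent.

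Gene lists (31 lists with 820 entries, 2 of them not found) were written before the data were examined, in classes of interferon, antigen presentation, signalling, stem and progenitor, cell-cycle, methylation, stress, metabolic and translation genes, markers of other marrow cell types and sample quality. Each was tested with camera in limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), again with an estimated correlation, and with fry, adjusted over the 31 lists of a comparison. The list p-values in the text are camera's with an estimated correlation where that call held. Both are printed where only the preset correlation gave a call, and the preset one alone where it gave none. Lists that the text does not name had no call with an estimated correlation in the 8 main comparisons. Counts of members past the test over all genes stand beside those adjusted over the list alone. Lists can share members, Ifih1 and Ddx58 for example being in both the interferon-stimulated and the nucleic acid sensing list. Calls of such lists are not independent.

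Named genes followed a rule fixed before the data were examined. In the 8 main comparisons it took up to 10 rises and 10 falls with an adjusted p under 0.05, a mean log2 CPM of at least 2, no predicted-gene symbol and no overlap between the libraries of the groups (for the genotype average, the same sign in each of the 4 treatments), and up to 4 members with the smallest p of each list described. In the other comparisons it took up to 5 rises and 5 falls, and Dnmt3a, Dnmt1 and Jak2 were always included. The text gives those of them that describe each gene group. Some of these genes are not reported here.

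Totals ran from 17782394 to 73910928 counts. A count of 0 in the smallest library allows up to 0.173 CPM (3 counts). Wilson 95% intervals on single libraries cover counting error only, since reads without molecular identifiers are not independent molecules, and replicate libraries differed by far more than counting error (chi-square per degree of freedom of at least 19.6 in each replicate pair). Each of the 17 planned comparisons was recomputed with RLE size factors, without the filter on low counts, with DESeq2 1.42.0, with limma voom and quality weights, with a replicate block, on the compared groups alone (not the genotype average, which uses all groups) and with each library of its groups left out in turn, and the 3 added ones were not. Settings added later were protein-coding rows only, no VF vehicle libraries 1 and 4, no libraries with fewer than 20000 detected rows, and list tests without the library labelled VFDM IFN 3.

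The model was tested on simulated data with 22172 genes, the design of the study and the dispersion estimated for each gene (common value 0.418). Changed genes were drawn only from rows at about the expression limit of the named-gene rule or above, so the shares do not cover lower rows. No outlying libraries were simulated, so the false shares may not hold for the VF vehicle contrasts. For VF IFN the model called 54% of genes changed by 1 log2 unit and 75% of those changed by 2, with 4.44% of calls false. For VF AZA the values were 48%, 81% and 3.73%, and for VFDM COMBO 44%, 68% and 2.61%. All columns of the table were used. No variants, splicing or DNA methylation were analysed here.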

Results

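Bulk RNA sequencing was done on long-term haematopoietic stem cells (LT-HSCs), sorted as lineage-negative, Sca1- and Kit-positive cells with CD150 and without CD48, from mice transplanted with mutant marrow and a 10-fold excess of wild-type marrow. The mutant cells, named VF in the labels, carried an inducible mutant human JAK2, the kinase that drives myeloproliferative neoplasms, and a GFP reporter. VFDM cells carried a deletion of Dnmt3a, a de novo DNA methyltransferase, as well. From 4 weeks after transplant the mice received vehicle, pegylated interferon alpha (IFN, 25 µg/kg each week), 5-azacytidine (AZA, 2 mg/kg each day), a nucleoside that depletes DNA methyltransferases, or both (COMBO) for 8 weeks. The 31 libraries fell into 8 groups of 4, except VFDM COMBO with 3, and held 17782394 to 73910928 counts each. Between 17087 and 28851 rows were detected in a library. Levels below are CPM (mean ± SD) and changes are log2 fold changes ± SE from edgeR, with adjusted p over 22172 genes. A "list adjusted p" is camera's with an estimated correlation, and a "camera adjusted p" is camera's with the preset correlation. Coordinates are mm10.

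Dnmt3a (ENSMUSG00000020661, chromosome 12, 3806007 to 3914443) had a lower mean in VFDM than in VF libraries in each of the 4 treatments, with an average log2 fold change of -1.08 ± 0.11 (adjusted p = 1.03e-07). The vehicle levels were 117 ± 5.33 against 234 ± 68.9 CPM, the VF vehicle libraries running from 162 to 297 and the VFDM vehicle libraries from 109 to 120. The vehicle difference, with a log2 SE of 0.21, passed the test (adjusted p = 0.0113), but not when VF vehicle library 1 or 4 or VFDM vehicle library 1, 3 or 4 was left out. The highest adjusted p was 0.106 (without VF vehicle library 4). VF IFN libraries held 160 to 178 CPM, VF AZA 176 to 223 and VF COMBO 104 to 193. VFDM AZA libraries held 83.4 to 107 CPM and VFDM COMBO 23 to 57. In VFDM IFN, libraries 1, 2 and 4 held 102 to 111 CPM and the library labelled VFDM IFN 3 held 162 (counting interval 159 to 166, Wilson 95%), a level of the VF libraries. That library also had VF levels of the CreERT2 transgene (113 CPM, with 212 to 244 in the other VFDM IFN libraries) and of Ifi204 (12.5 CPM, with 68.9 to 79.6 in the others and 6.39 to 13.8 in VF IFN). Its target level went against its label. Dnmt1, the maintenance methyltransferase, passed the test in no planned comparison.

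**Figure D1:**
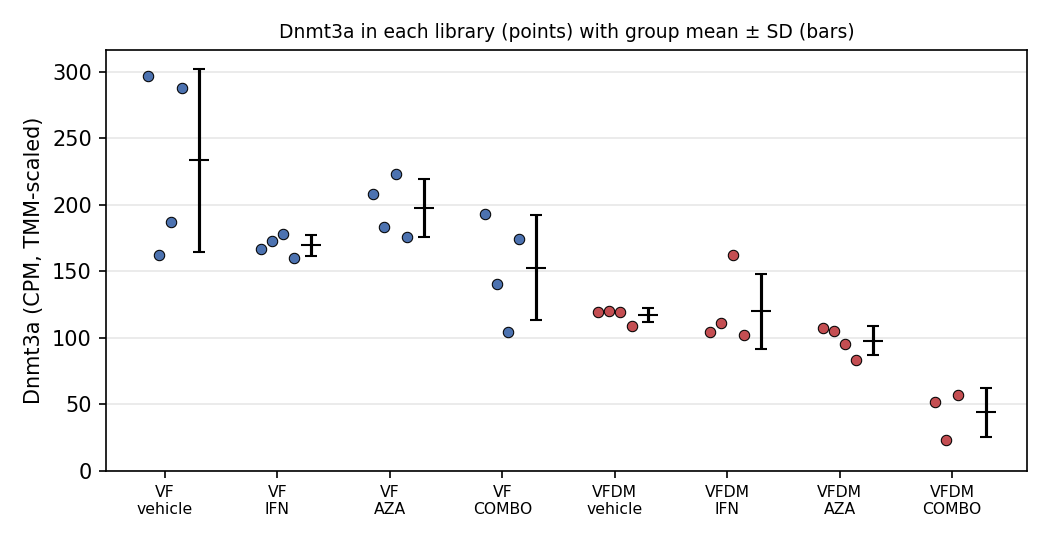
Dnmt3a level of each library (points, CPM) by group, with the group mean and SD (bars); VF groups are blue and VFDM groups red. The library labelled VFDM IFN 3 sits at 162 CPM, above the other 3 VFDM IFN libraries at 102 to 111 CPM.

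Interferon alone in VF cells was compared with vehicle to give the response of mutant LT-HSCs with intact Dnmt3a. The clearest rises were antiviral effectors and their regulators. Irf7, the transcription factor that amplifies interferon production (chromosome 7, 141262706 to 141266481), rose 10.8-fold (163 ± 18.9 against 15.2 ± 5.46 CPM, n = 4 and 4; log2 fold change 3.43 ± 0.32, adjusted p = 1.21e-08). Oas2, which makes the activator of RNase L, rose from 30.3 ± 13.9 to 242 ± 41.1 CPM (adjusted p = 7.95e-11). Ifit3, an inhibitor of viral translation, rose 22.3-fold (log2 fold change 4.48 ± 0.78, adjusted p = 8.47e-04). Of 45 type I interferon-stimulated genes, 41 rose, 0 fell and 4 did not pass, and 43 rose adjusted over the list alone, with a median log2 change of 1.58 (list adjusted p = 4.54e-09). Among 24 nucleic acid sensing genes 10 rose and 0 fell, with 11 up and 1 down adjusted over the list alone (list adjusted p = 7.3e-05), including the RNA sensors Ifih1 (1.58 ± 0.15) and Ddx58 (1.21 ± 0.14). Interferon-gamma-inducible GTPases rose for 9 of 19 members and fell for 0 (10 up adjusted over the list alone; list adjusted p = 0.00301), among them Irgm1, which guards against intracellular pathogens (1.66 ± 0.16, adjusted p = 6.21e-09). In the list of MHC class I presentation, 5 of 22 rose and 0 fell, with 6 up adjusted over the list alone (camera adjusted p = 0.00118, but adjusted p = 0.209 with an estimated correlation). The peptide transporter Tap1 changed by 0.69 ± 0.12 (adjusted p = 6.96e-04).

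Stem and lineage genes moved beside the interferon genes in VF IFN. Of 40 LT-HSC genes 6 rose and 1 fell (9 up and 4 down adjusted over the list alone). The list as a whole did not pass, its median of -0.08 and mean of -0.16 having the opposite sign to camera's direction (camera adjusted p = 0.289). Ly6a, which encodes Sca1 and is itself interferon-inducible, rose 3.62-fold (58.3 ± 5.83 against 16.1 ± 5.48 CPM). Sca1 was part of the sort, so whether the gate held the same cells in both groups is uncertain. Megakaryocyte and platelet markers rose for 6 of 26 members, 0 fell and 13 rose adjusted over the list alone (list adjusted p = 0.0278). Plek, a platelet signalling protein, went from 53.9 ± 13.2 to 313 ± 50.2 CPM (log2 fold change 2.54 ± 0.40, adjusted p = 2.57e-04). Erythroid markers, of which 2 of 24 rose, 0 fell and 6 rose adjusted over the list alone, passed with the preset correlation only (camera adjusted p = 1.82e-06, but adjusted p = 0.125 with an estimated correlation). Monocyte and neutrophil markers had no member past the test over all genes (7 and 7 up adjusted over each list alone), with camera adjusted p = 2.5e-10 and 1.75e-07, and adjusted p = 0.0403 and 0.125 with an estimated correlation. Bcl2, a survival protein, rose by 0.96 ± 0.14 (adjusted p = 2.84e-05), while the STAT5 target Cish fell from 53.3 ± 16.1 to 19.7 ± 4.12 CPM (log2 fold change -1.44 ± 0.29, adjusted p = 0.00288). Mouse Jak2 rose by 0.52 ± 0.12 (adjusted p = 0.00803). Of 710 small and ribosomal RNAs tested 47 were lower and 0 higher, the class as a whole not being tested. Among the 47 were the ribonuclease RNA Rmrp (-4.02 ± 0.83) and the 5S gene n-R5s118 (-3.57 ± 0.61), copies of which cannot be separated. Small and ribosomal RNAs took 9.67%, 14.9% and 15.9% of the counts of VF vehicle libraries 1, 2 and 4 and 4.31% in library 3. Cytosolic ribosomal protein genes fell for 14 of 45 members with 0 up (23 down adjusted over the list alone; camera adjusted p = 4.07e-19, but adjusted p = 0.113 with an estimated correlation), for example Rps2 (-0.97 ± 0.18, adjusted p = 0.00122).

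In all, 538 genes differed between VF IFN and VF vehicle, 281 higher and 257 lower. The count was 1040 without VF vehicle library 3, 292 without VF vehicle library 4, 273 without VF IFN library 1 and 351 without VF IFN library 4. It was 205 without VF vehicle libraries 1 and 4 together (a setting chosen after the data were seen, under which Rps2 and Jak2 no longer passed). It was 1522 in the fit without the libraries with fewer than 20000 detected rows, none of which is in these groups.

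Azacytidine alone in VF cells asked what the methyltransferase inhibitor does to mutant LT-HSCs. Rises among protein-coding genes were small. Phf11d, a gene of an interferon-responsive cluster, rose 2.8-fold (35.8 ± 7.67 against 12.6 ± 7.31 CPM; log2 fold change 1.48 ± 0.27, adjusted p = 0.00225). Zmynd19 rose 2.16-fold (log2 fold change 1.11 ± 0.17, adjusted p = 6.68e-04). The survival gene Bcl2 rose by 0.72 ± 0.14 (adjusted p = 0.00399). Type I interferon-stimulated genes as a list did not pass: 3 of 45 rose and 0 fell, 5 rose and 2 fell adjusted over the list alone, and the median of -0.02 had the opposite sign to camera's direction (camera adjusted p = 0.294). In the LT-HSC list 4 of 40 rose and 0 fell (8 up and 1 down adjusted over the list alone; camera adjusted p = 0.00147, but adjusted p = 0.477 with an estimated correlation). Angpt1, a niche ligand made by stem cells, went from 448 ± 137 to 727 ± 103 CPM (log2 fold change 0.70 ± 0.14, adjusted p = 0.00733), a call that ended without VF AZA library 2 (adjusted p = 0.0511). Of 10 methylation-silenced germline genes 0 rose and 0 fell (0 up adjusted over the list alone; camera adjusted p = 0.943), and of 32 imprinted genes 1 rose and 0 fell (2 up adjusted over the list alone; camera adjusted p = 0.943). Among the falls were 51 of the 710 small and ribosomal RNAs tested (0 higher), such as the 5S gene n-R5s118 (-4.36 ± 0.64), the small nucleolar RNA Rnu3a (-3.55 ± 0.50) and Scarna2 (-2.16 ± 0.30, adjusted p = 2.36e-04). Small and ribosomal RNAs took 2.09% to 3.34% of the counts of VF AZA libraries, beside 9.67%, 14.9% and 15.9% in VF vehicle libraries 1, 2 and 4 and 4.31% in library 3. Cytosolic ribosomal proteins fell for 15 of 45 members, 0 rose and 31 fell adjusted over the list alone (camera adjusted p = 2.03e-17, but adjusted p = 0.477 with an estimated correlation), and Rplp2 fell by 1.11 ± 0.18 (adjusted p = 7.72e-04). Dnmt3a (-0.24 ± 0.21, adjusted p = 0.68) and Dnmt1 (-0.03 ± 0.17, adjusted p = 0.961) did not pass the test.

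The VF AZA count was 265 genes, 65 higher and 200 lower, and it depended on the setting. It was 0 with edgeR on the 8 VF vehicle and VF AZA libraries alone, 3 without the libraries with fewer than 20000 detected rows, 843 with DESeq2 and 23 with limma voom. In the full fit 3129 genes had an unadjusted p under 0.05. Leaving out VF vehicle library 3 gave 942, VF vehicle library 4 gave 112, and VF AZA libraries 1, 2 and 3 gave 465, 85 and 104. A separate check of protein-coding genes only, added after the data were seen, gave 37.

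The combination in VF cells was compared with vehicle and with each drug to show what was added to either. Interferon genes rose as a group: 39 of 45 rose and 0 fell, 42 rose adjusted over the list alone, and the median change was 1.5 (list adjusted p = 5.29e-07). Irf7 rose from 15.2 ± 5.46 to 142 ± 24.3 CPM (log2 fold change 3.23 ± 0.32, adjusted p = 5.44e-08) and the helicase Ddx60 by 2.11 ± 0.16 (adjusted p = 2.39e-10). Nucleic acid sensing genes rose for 9 of 24 members and fell for 0 (11 up and 2 down adjusted over the list alone; list adjusted p = 0.00394). Beside this, stem-cell genes went both ways: 4 of 40 LT-HSC genes rose and 6 fell, 8 and 12 adjusted over the list alone (camera adjusted p = 0.334). Hlf, a transcription factor that marks long-term stem cells, fell from 278 ± 21.3 to 134 ± 46.2 CPM (log2 fold change -1.06 ± 0.22, adjusted p = 0.00205). Esam, a stem-cell adhesion molecule, fell 2.95-fold (log2 fold change -1.56 ± 0.29, adjusted p = 6.52e-04), while the co-receptor Tgfbr3 rose by 1.38 ± 0.18 (adjusted p = 6.71e-06). Erythroid markers rose for 11 of 24 members with 0 down (12 up adjusted over the list alone; camera adjusted p = 7.59e-09, but adjusted p = 0.106 with an estimated correlation). Among them were the carbonic anhydrase Car1 (73.4 ± 70.5 against 0.436 ± 0.546 CPM; log2 fold change 7.93 ± 1.48, adjusted p = 0.00169) and the transferrin receptor Tfrc (1.64 ± 0.28). The JAK2-STAT5 targets fell for 3 of 22 members and rose for 0 (3 down adjusted over the list alone; camera adjusted p = 0.2), Pim1, a survival kinase, going from 292 ± 65.4 to 140 ± 41.9 CPM (log2 fold change -1.06 ± 0.18, adjusted p = 3e-04). Mouse Jak2 rose by 0.69 ± 0.12 (adjusted p = 2.88e-04), and Dnmt3a changed by -0.61 ± 0.21 (adjusted p = 0.0641).

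Markers of other blood cells were unevenly spread over the VF COMBO libraries. T and NK cell markers rose for 4 of 16 members with 0 down (7 up adjusted over the list alone; camera adjusted p = 0.0342, but adjusted p = 0.626 with an estimated correlation). These came from VF COMBO library 1, where Cd3e stood at 23.9 CPM and Trbc2 at 11.7 CPM against 0 in libraries 2, 3 and 4. Without it Cd4 went from 7.84 ± 1.89 to -0.22. The mean log2 level of the LT-HSC list in the VF COMBO libraries was 5.88, 5.10, 4.53 and 5.50, and that of the erythroid list 1.62, 3.74, 4.49 and 3.31. Of the 710 small and ribosomal RNAs tested 79 were lower and 1 higher. The 1838 genes called (923 higher, 915 lower) became 1180 and 823 without VF vehicle library 1 or 4, 1117 and 3007 without VF COMBO library 3 or 4, 283 with limma voom and 228 without the libraries with fewer than 20000 detected rows. The median log2 change of all genes was -0.114 in this comparison, so that values near it lie at the middle of the distribution.

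Set against IFN alone, VF COMBO had 2 genes past the test, with 2490 at an unadjusted p under 0.05 and 189 by DESeq2. The higher of them was Vim, an intermediate filament (403 ± 85.6 against 208 ± 12.2 CPM; log2 fold change 0.95 ± 0.17, adjusted p = 0.0209), whose call ended without VF IFN library 1, 2, 3 or 4 (adjusted p = 0.143, 0.135, 0.0812 and 0.0544). The other was Gm22009 (-1.46 ± 0.21, adjusted p = 0.00168), outside the rule for named genes and chosen after its values were seen. The count was 1 without any of the 4 VF IFN libraries, 58 without VF COMBO library 1, 4 without library 2 and 276 without library 4. Against AZA alone there were 411 genes, 235 higher and 176 lower. Of the interferon-stimulated list 35 of 45 rose and 0 fell (43 up adjusted over the list alone; list adjusted p = 6.32e-08), with Usp18, the negative regulator of interferon signalling, up by 3.50 ± 0.27 (adjusted p = 2.6e-10). Erythroid markers rose for 10 of 24 and fell for 0 (15 up adjusted over the list alone; list adjusted p = 0.0328). LT-HSC genes fell for 5 and rose for 1 of 40 (13 down and 2 up adjusted over the list alone; list adjusted p = 0.0405), and Hlf fell by 1.21 ± 0.22 (adjusted p = 0.00107). Trib2, a pseudokinase that drives decay of a myeloid factor, rose by 6.67 ± 0.83 (adjusted p = 2.09e-05). This count was 267 without VF AZA library 2, 805, 247, 218 and 1017 without VF COMBO libraries 1 to 4 in turn, and 45 without the libraries with fewer than 20000 detected rows.

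Whether the drugs added up in VF cells was tested with a non-additivity term, which 19 genes passed (15 higher and 4 lower than the sum). The largest were small RNAs such as n-R5s118 (4.38 ± 0.82, adjusted p = 0.0235), which had fallen with each drug alone, and 13 of the 19 were small or ribosomal RNAs. Small and ribosomal RNAs took a mean of 11.2% of counts in VF vehicle, 4.34% in VF IFN, 2.7% in VF AZA and 3.08% in VF COMBO. A high level in VF vehicle alone gives falls with each drug and a positive term, and this was not separated. In VFDM IFN and VFDM AZA 0 such RNAs were called lower than in VFDM vehicle. The call of n-R5s118 ended without VF vehicle library 2, VF IFN library 1 or 3 or VF AZA library 2, 3 or 4 (adjusted p = 0.116, 0.0966, 0.09, 0.0879, 0.0782 and 0.0565). Among protein-coding genes Bcl2 lay below the sum, at -1.08 ± 0.20 (adjusted p = 0.0207). Its call ended without VF IFN library 1 or 3, VF AZA library 2, 3 or 4 or VF COMBO library 3 (adjusted p = 0.0923, 0.0675, 0.053, 0.0782, 0.0557 and 0.0517). No gene passed with limma voom, with protein-coding rows only or with the VF libraries alone, and 237 passed with DESeq2. The count was 192, 29 and 102 without VF vehicle library 3 and VF COMBO libraries 1 and 4, and 0 to 8 without VF IFN libraries 1 to 4, VF AZA libraries 2 to 4 or VF COMBO library 3.

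The libraries labelled VFDM IFN were compared with VFDM vehicle. They include the library labelled VFDM IFN 3, whose Dnmt3a, CreERT2 and Ifi204 levels were those of VF cells, so it is uncertain whether all 4 hold Dnmt3a-deleted cells. Without it 172 genes passed, and the genes named here stayed past the threshold. Irf7 rose 14.4-fold (179 ± 13.4 against 12.5 ± 3.06 CPM, n = 4 and 4; log2 fold change 3.85 ± 0.32, adjusted p = 2.81e-09). Usp18 rose from 8.72 ± 2.22 to 83.5 ± 8.03 CPM (log2 fold change 3.26 ± 0.26, adjusted p = 3.08e-10), and Isg15, a ubiquitin-like modifier, rose by 3.32 ± 0.39 (adjusted p = 7.92e-07). Of 45 type I interferon-stimulated genes 42 rose, 0 fell and 44 rose adjusted over the list alone, with a median of 1.39 (list adjusted p = 5.8e-11). Class I presentation rose for 7 of 22 members and fell for 0 (13 up adjusted over the list alone; list adjusted p = 3.37e-04), Tap1 from 126 ± 1.45 to 247 ± 8.56 CPM. Nucleic acid sensing genes rose for 8 of 24 and fell for 0 (9 up adjusted over the list alone; list adjusted p = 4.48e-05). The inducible GTPases rose for 8 of 19 and fell for 0 (10 up adjusted over the list alone; list adjusted p = 0.00272). In the LT-HSC list 3 of 40 rose and 1 fell (4 up and 3 down adjusted over the list alone; camera adjusted p = 0.154). Ly6a rose 3.96-fold (1.98 ± 0.27, adjusted p = 9.29e-06) and Hlf fell from 450 ± 39.9 to 222 ± 33.3 CPM (log2 fold change -1.02 ± 0.21, adjusted p = 0.00768). Lineage markers rose beside these. Gata1, the erythroid and megakaryocytic master factor, rose 4.17-fold (34.1 ± 12.6 against 8.18 ± 1.18 CPM; log2 fold change 2.06 ± 0.34, adjusted p = 2.51e-04). Pf4, a platelet chemokine, rose 9.98-fold (3.32 ± 0.56, adjusted p = 0.00124), and Plac8, a marker of early progenitors, rose by 2.59 ± 0.30 (adjusted p = 1.87e-06). Erythroid markers rose for 2 of 24 and fell for 0 (13 up adjusted over the list alone; list adjusted p = 0.00894). Megakaryocyte markers rose for 5 of 26 with 0 down (11 up and 1 down adjusted over the list alone; list adjusted p = 0.0215).

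Neutrophil markers rose for 10 of 21 members in VFDM IFN with 0 down (13 up adjusted over the list alone; list adjusted p = 0.00268). The granule gene Ngp stood at 44.4 ± 43.6 against 0.257 ± 0.181 CPM, but the spread was wide, the neutrophil list mean being 2.46, 1.5, 0.85 and 3.76 in the 4 libraries on the log2 scale. The call of Ngp ended without VFDM IFN library 4 or any VFDM vehicle library (highest adjusted p = 0.114, without VFDM vehicle library 2). Monocyte markers had 0 members past the test over all genes and 8 adjusted over the list alone (list adjusted p = 0.0096). In total 214 genes differed, 203 higher and 11 lower, and 120 or 142 without VFDM vehicle library 2 or 3. The fit on the 8 VFDM vehicle and IFN libraries alone called 1092, limma voom 1950, and the fit without the libraries with fewer than 20000 detected rows, all from other groups, 631. Dnmt3a in VFDM IFN changed by 0.04 ± 0.21 (adjusted p = 1), a mean that includes the library labelled VFDM IFN 3.

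**Figure D2:**
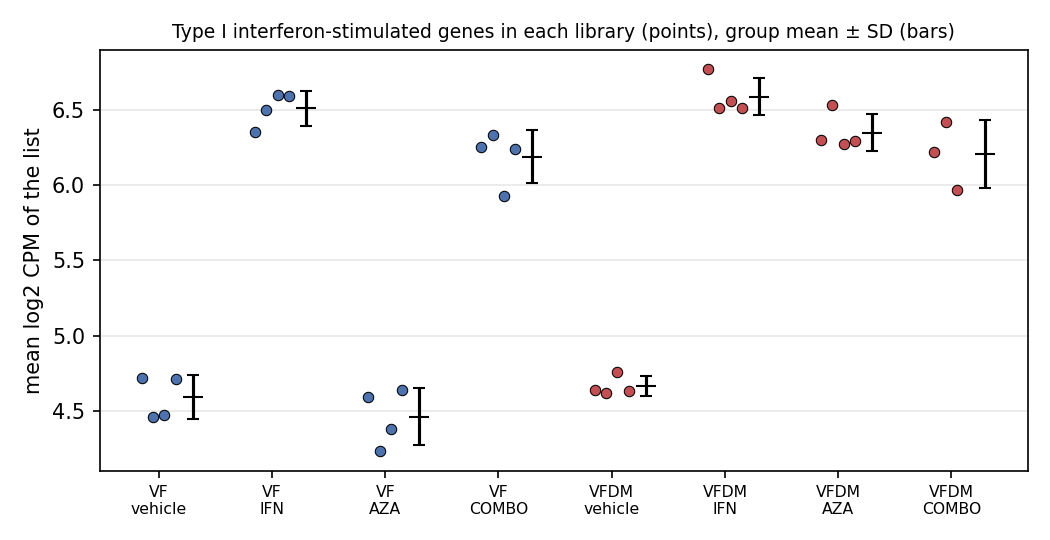
Mean log2 CPM of the 45 type I interferon-stimulated genes in each library (points) with the group mean and SD (bars); VF groups are blue and VFDM groups red. The VF AZA libraries lie at 4.23 to 4.64, near the vehicle libraries, and the VFDM AZA libraries at 6.27 to 6.53, near the IFN libraries.

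The libraries labelled VFDM AZA were compared with VFDM vehicle, and interferon genes were higher in them. The data do not settle whether azacytidine or an exposure to interferon raised these genes. Irf7 rose 11.3-fold (141 ± 20.3 against 12.5 ± 3.06 CPM, n = 4 and 4; log2 fold change 3.50 ± 0.32, adjusted p = 2.23e-08). Oas2 rose from 25.5 ± 2.27 to 212 ± 9.49 CPM (log2 fold change 3.06 ± 0.23, adjusted p = 1.49e-10), and the antiviral GTPase Mx1 by 3.56 ± 0.50 (adjusted p = 3.85e-05). Of the 45 type I interferon-stimulated genes 39 rose and 0 fell, and 43 rose adjusted over the list alone, with a median of 1.47 (list adjusted p = 1.85e-09). The difference from VF cells was tested directly. In the AZA response of VFDM minus VF 28 of 45 were higher and 0 lower (38 higher adjusted over the list alone), by a median of 1.44 (list adjusted p = 7.66e-07). Irf7 was at 3.77 ± 0.43 (adjusted p = 3.89e-06) and Usp18 at 3.38 ± 0.35 (adjusted p = 1.11e-06). In all 129 genes passed that term, 125 higher and 4 lower. Of the 125, 16 were small or ribosomal RNAs, whose shares were high in VF vehicle libraries 1, 2 and 4. The count was 269 without VF vehicle library 3, 70 without VF vehicle libraries 1 and 4, 61 without the libraries with fewer than 20000 detected rows, 68 on the compared groups alone, 81 on protein-coding rows and 381 with DESeq2. Nucleic acid sensing genes rose in VFDM AZA for 7 of 24 (0 down, 9 up and 1 down adjusted over the list alone; list adjusted p = 0.00146). Inducible GTPases rose for 9 of 19 (0 down, 10 up adjusted over the list alone; list adjusted p = 0.00409), as did class I presentation for 5 of 22 (0 down, 7 up adjusted over the list alone; list adjusted p = 0.00704).

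Erythroid markers rose with the interferon genes in VFDM AZA, 10 of 24 going up and 0 down (15 up adjusted over the list alone; list adjusted p = 0.00411). Gata1 went from 8.18 ± 1.18 to 37.7 ± 18.3 CPM (log2 fold change 2.20 ± 0.34, adjusted p = 1.22e-04). The membrane skeleton gene Sptb rose 14.3-fold (3.84 ± 0.57, adjusted p = 1.28e-04) and the erythroid membrane protein gene Ermap by 6.21 ± 1.20 (adjusted p = 0.00653). In the difference between genotypes 6 of 24 erythroid markers were higher and 0 lower (13 higher adjusted over the list alone; camera adjusted p = 3.77e-10, but adjusted p = 0.0703 with an estimated correlation). Gata1 was at 2.24 ± 0.47 (adjusted p = 0.0109), a call lost without VFDM AZA library 3 (adjusted p = 0.0543). Ribosome biogenesis genes rose for 1 of 34 (0 down, 8 up adjusted over the list alone) and passed as a list with a median of 0.29 (list adjusted p = 0.0275). The LT-HSC list held 2 that rose and 0 that fell of 40 (2 and 2 adjusted over the list alone; camera adjusted p = 0.823), Ly6a up by 1.82 ± 0.27 (adjusted p = 4.98e-05) and Tgfbr3 by 1.07 ± 0.18 (adjusted p = 5.27e-04). Of 10 germline genes 0 rose and 0 fell (0 up adjusted over the list alone; camera adjusted p = 0.373). Dnmt3a (-0.25 ± 0.21, adjusted p = 0.827), Dnmt1 (0.28 ± 0.17, adjusted p = 0.684) and Jak2 (0.28 ± 0.12, adjusted p = 0.381) did not pass. The count was 205 genes, 189 higher and 16 lower, and 112, 129 and 134 without VFDM vehicle library 2, 3 or 4 and 134 without VFDM AZA library 3. The 8 VFDM vehicle and AZA libraries alone gave 478, DESeq2 418 and limma voom 796.

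A comparison of VFDM AZA with VFDM IFN was added after these values were seen. By edgeR 0 genes passed. An unadjusted p under 0.05 was found for 1053 of the 22172 genes, about the share that chance alone gives. Neither DESeq2 nor limma voom was run on this comparison. The interferon-stimulated list differed by a median of -0.20, with 0 up and 0 down of 45, and as many adjusted over the list alone (camera adjusted p = 0.0156, but adjusted p = 0.568 with an estimated correlation). Neutrophil markers were lower in VFDM AZA, none past the test over all genes but 15 of 21 adjusted over the list alone (list adjusted p = 5.8e-04). The mean log2 level of that list ran from -3.22 to -1.76 in VFDM AZA and from 0.85 to 3.76 in VFDM IFN, S100a9 for example standing at 0.0569 ± 0.114 CPM in VFDM AZA, so the size of the difference is uncertain.

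The combination in VFDM cells gave the largest count of the 17 planned comparisons, with stem-cell transcripts among its largest falls. Hlf fell 12.7-fold (35.4 ± 4.2 against 450 ± 39.9 CPM, n = 3 and 4; log2 fold change -3.67 ± 0.27, adjusted p = 5.8e-11; chromosome 11, 90336536 to 90390895). Mecom, a factor needed for stem-cell maintenance, fell 8.3-fold (log2 fold change -3.05 ± 0.33, adjusted p = 9.11e-08). Procr, the protein C receptor used to mark stem cells, fell from 36.2 ± 2.92 to 0.176 ± 0.228 CPM (log2 fold change -7.54 ± 0.87, adjusted p = 3.33e-07). Esam fell 17.8-fold (-4.15 ± 0.36, adjusted p = 1.13e-09). Of 40 LT-HSC genes 1 rose and 26 fell, 1 and 29 adjusted over the list alone, with a median of -1.53 (list adjusted p = 8.44e-04). In the COMBO response of VFDM minus VF 0 were higher and 16 lower of the 40 (1 and 22 adjusted over the list alone), by a median of -1.08 (list adjusted p = 0.00108). Hlf was at -2.61 ± 0.32 (adjusted p = 1.5e-05) and Erg, a stem-cell ETS factor, at -1.50 ± 0.24 (adjusted p = 2.63e-04). Erythroid markers rose for 23 of 24 with 0 down (23 up adjusted over the list alone), by a median of 5.55 (list adjusted p = 5.94e-04). Gata1 rose 10.9-fold (log2 fold change 3.45 ± 0.37, adjusted p = 3.77e-08), Car1 went from 0.877 ± 0.895 to 238 ± 38.4 CPM and Tfrc by 2.40 ± 0.30 (adjusted p = 7.66e-07). The genotype term held 8 erythroid markers higher and 0 lower (12 higher adjusted over the list alone; list adjusted p = 0.0322), including Gata1 (2.26 ± 0.48, adjusted p = 0.00482). Neutrophil markers rose for 14 of 21 with 0 down (15 up adjusted over the list alone; list adjusted p = 0.0228), S100a9 standing at 204 ± 250 against 0.5 ± 0.454 CPM.

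**Figure D3:**
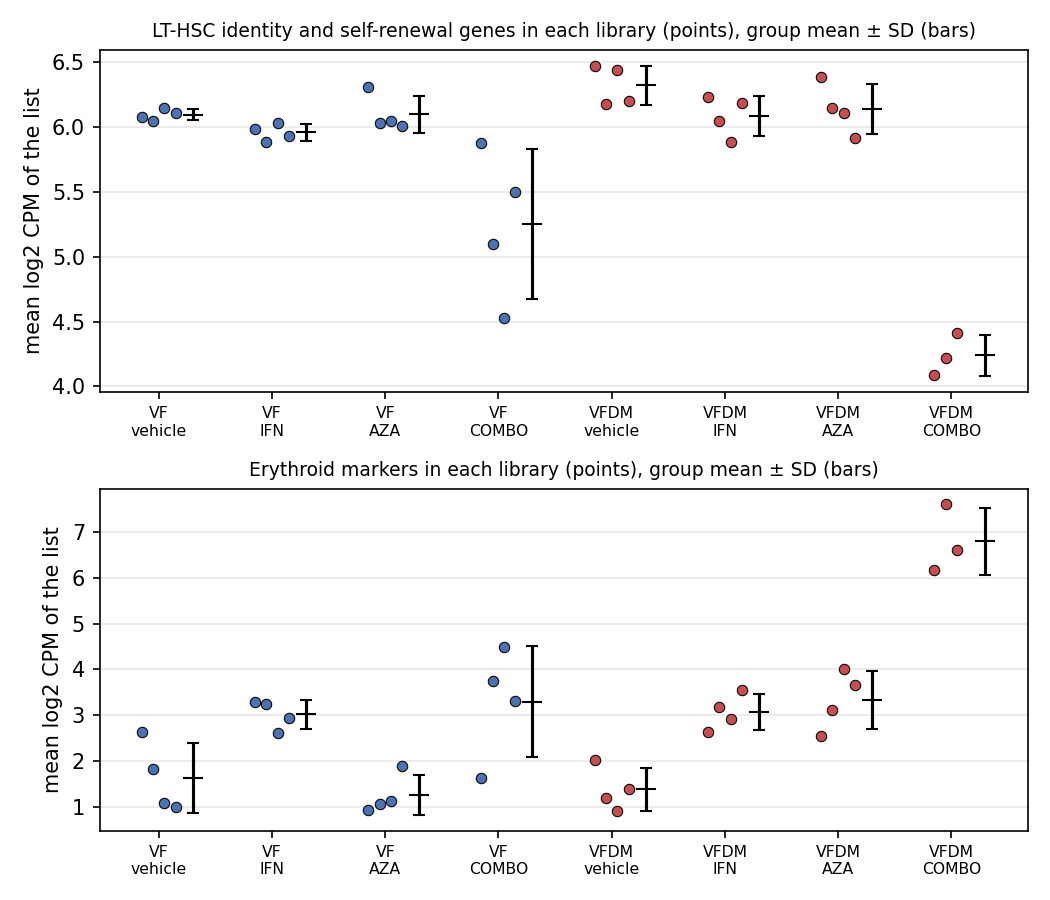
Mean log2 CPM of the 40 LT-HSC genes (top) and 24 erythroid markers (bottom) in each library (points), with the group mean and SD (bars); VF groups are blue and VFDM groups red. The 3 VFDM COMBO libraries lie at 4.09 to 4.41 on the LT-HSC list, below the VFDM vehicle libraries at 6.18 to 6.47, and at 6.17 to 7.61 on the erythroid list.

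Cell-cycle and ribosome biogenesis genes were counted in VFDM COMBO as well. Of 30 S-phase genes 11 rose and 0 fell (17 up adjusted over the list alone; camera adjusted p = 1.32e-10, but adjusted p = 0.169 with an estimated correlation). Mcm7, a subunit of the replicative helicase, rose by 0.70 ± 0.14 (adjusted p = 4.23e-04). Of 30 G2 and M phase genes 9 rose and 0 fell (12 up adjusted over the list alone; camera adjusted p = 1.17e-09, but adjusted p = 0.261 with an estimated correlation). The proliferation marker Mki67 went from 902 ± 187 to 1740 ± 332 CPM (log2 fold change 0.95 ± 0.23, adjusted p = 0.00378). Ribosome biogenesis genes rose for 16 of 34 with 0 down (26 up adjusted over the list alone; list adjusted p = 0.0331), the helicase Ddx21 by 0.92 ± 0.16 (adjusted p = 1.23e-04). Targets of JAK2-STAT5 signalling went both ways, 3 up and 6 down of 22 (4 and 6 adjusted over the list alone; camera adjusted p = 0.604). Pim1 fell from 220 ± 14.6 to 68.4 ± 5.34 CPM (log2 fold change -1.69 ± 0.20, adjusted p = 3.11e-07) and Socs2, a feedback inhibitor of cytokine receptors, changed by -4.26 ± 0.79 (adjusted p = 4.82e-04). In the imprinted list 7 of 32 fell and 0 rose (8 down adjusted over the list alone; camera adjusted p = 0.0118, but adjusted p = 0.169 with an estimated correlation), among them Cdkn1c, a cell-cycle inhibitor (-3.34 ± 0.78, adjusted p = 0.00254). Multipotent progenitor genes split, 4 up and 7 down of 20 (4 and 9 adjusted over the list alone; camera adjusted p = 0.466), with a median of -0.69 and a mean of 0.51. Cd34, a progenitor antigen, fell 7.67-fold (21.4 ± 4.85 against 164 ± 52.3 CPM) and Plac8 rose by 3.26 ± 0.32 (adjusted p = 2.48e-08). The methylation machinery list had 3 up and 4 down of 25, with a median of 0.04 and a mean of -0.15 (3 up and 5 down adjusted over the list alone; camera adjusted p = 0.708). The methylcytosine dioxygenase Tet1 fell by 1.33 ± 0.21 (adjusted p = 2.5e-05), the reader Mbd2 rose by 0.95 ± 0.15 (adjusted p = 3.13e-05), and Dnmt3a fell from 117 ± 5.33 to 43.9 ± 18.3 CPM (log2 fold change -1.41 ± 0.24, adjusted p = 5.09e-05).

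Interferon genes rose in VFDM COMBO too, 37 of 45 up and 0 down (38 up adjusted over the list alone; list adjusted p = 4.24e-05), Irf7 by 3.75 ± 0.33 (adjusted p = 3.45e-09). The inducible GTPases split, 3 up and 5 down of 19 (3 and 5 adjusted over the list alone; camera adjusted p = 0.877). Irgm1 rose by 1.59 ± 0.16 (adjusted p = 2.15e-08), and Irf1, a factor induced by both interferon types, fell by 1.31 ± 0.24 (adjusted p = 2.04e-04). Against the sum of the single drugs 38 of 45 interferon-stimulated genes were lower and 0 higher (41 lower adjusted over the list alone), by a median of -1.67 (list adjusted p = 1.09e-07) after each group given 1 drug had shown a rise of this list. The list stood close to VFDM IFN in the libraries labelled VFDM AZA, so the sum counts a rise of this kind from both drugs. LT-HSC genes lay below the sum for 15 and above it for 0 of 40 (29 and 1 adjusted over the list alone), by a median of -1.24 (list adjusted p = 3.78e-05). Esam was at -3.07 ± 0.43 (adjusted p = 3.17e-05). The erythroid list had a median of -0.13 and a mean of 1.57 in this term, 5 markers lying above the sum and 0 below (5 and 0 adjusted over the list alone; camera adjusted p = 2.58e-04, but adjusted p = 0.305 with an estimated correlation). In all 451 genes passed, 37 above and 414 below the sum, against a median of all genes of -0.104, and 299, 297 and 299 without VFDM vehicle library 2 or 4 or VFDM IFN library 1.

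VFDM COMBO was also set against each drug alone. Against IFN 1748 genes differed, 355 higher and 1393 lower, and against AZA 1733, 431 higher and 1302 lower. LT-HSC genes were lower for 25 of 40 against IFN (0 higher, 29 lower and 2 higher adjusted over the list alone; list adjusted p = 2.2e-04). They were lower for 27 against AZA (1 higher, 29 lower and 1 higher adjusted over the list alone; list adjusted p = 7.65e-05). Hlf had log2 fold changes of -2.65 ± 0.25 (adjusted p = 2.68e-08) and -2.85 ± 0.26 (adjusted p = 9.11e-09), and Dnmt3a of -1.44 ± 0.24 (adjusted p = 8.92e-05) and -1.15 ± 0.23 (adjusted p = 0.00132). The immunity-related GTPase Irgm2 was at -1.30 ± 0.20 (adjusted p = 3.6e-05) against IFN and -1.35 ± 0.20 (adjusted p = 2.68e-05) against AZA. Erythroid markers were higher for 18 and 12 of 24 with 0 and 0 lower (22 and 16 higher adjusted over the list alone), with camera adjusted p = 5.42e-24 and 8.92e-17, and adjusted p = 0.00156 and 0.0082 with an estimated correlation. The count against IFN was 1112 without VFDM IFN library 1, 1092 and 1123 without VFDM COMBO libraries 3 and 4, and against AZA 1039 without VFDM COMBO library 3.

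Haemoglobin genes stood at 1040, 18500 and 3020 CPM in VFDM COMBO libraries 2, 3 and 4, and 4 Y-linked genes at 69, 296 and 141 counts, where each of the other 28 libraries held 0 to 4 such counts. Xist was at 3770, 3700 and 3680 CPM in the same 3 libraries. The 3551 genes called in VFDM COMBO against vehicle, 1224 higher and 2327 lower, were between 2531 and 3081 with any 1 of the 7 libraries left out. The count was 6062 without the libraries with fewer than 20000 detected rows, which leaves VFDM COMBO libraries 2 and 4. In the genotype difference of the COMBO response 830 genes passed, 277 higher and 553 lower, 30 of the 277 being small or ribosomal RNAs. That count was 524 without VF vehicle library 4, 328 without VF vehicle libraries 1 and 4, 298 on the compared groups alone, 262 with limma voom and 1833 with DESeq2. The interferon response differed between genotypes for 0 genes by edgeR, 33 by DESeq2 and 5 by limma voom, and for 70 by edgeR without VF vehicle library 3. In the edgeR test of all libraries 1149 of the 22172 genes had an unadjusted p under 0.05, about the share that chance alone gives.

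**Figure D4:**
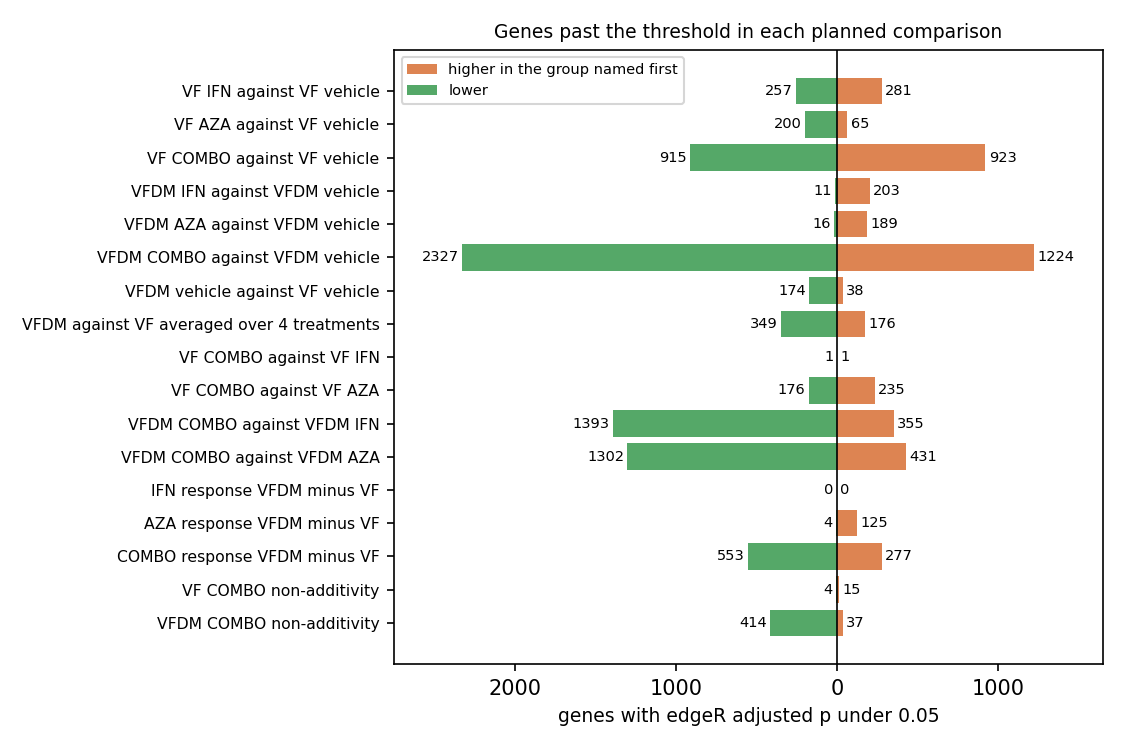
Number of genes past the edgeR test in each of the 17 planned comparisons, higher to the right and lower to the left. VFDM COMBO against vehicle has 1224 higher and 2327 lower, and the interferon response differs between genotypes for 0 genes.

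VFDM vehicle was compared with VF vehicle for the difference between the genotypes without treatment. Among the rises were genes of the Ifi200 cluster on chromosome 1, which encode sensors of nucleic acids. The data do not settle whether these came from Dnmt3a loss or from linked sequence carried with one genotype. Ifi204 (chromosome 1, 173747293 to 173766943) was 33.9-fold higher (36.5 ± 5.25 against 1.11 ± 0.42 CPM, n = 4 and 4; log2 fold change 5.08 ± 0.63, adjusted p = 9.21e-05). Ifi211 was 12-fold higher (3.58 ± 0.54, adjusted p = 4.33e-04) and Mndal at 213 ± 17.4 against 96.9 ± 35.5 CPM (log2 fold change 1.14 ± 0.19, adjusted p = 0.00117). The members of this family are near copies of each other, so the assignment of reads among them is uncertain. Slamf1, which encodes the sorting marker CD150 and lies on the same chromosome, went from 34.8 ± 10.1 to 75 ± 14 CPM (log2 fold change 1.11 ± 0.21, adjusted p = 0.0046). Cd48, which encodes the marker the sort excludes, lies in the same region. Its vehicle levels, chosen after they were seen, stood at 6.18 ± 1.57 CPM in VFDM and 2.82 ± 0.48 in VF vehicle (1.13 ± 0.48, adjusted p = 0.335). Plac8 was lower (22.2 ± 7.73 against 84 ± 25.3 CPM; log2 fold change -1.92 ± 0.30, adjusted p = 8.84e-04), as was Emilin2, a matrix glycoprotein (-3.28 ± 0.57, adjusted p = 0.00337). In the nucleic acid sensing list 4 of 24 were higher and 0 lower (6 and 1 adjusted over the list alone; list adjusted p = 0.0342). In the interferon-stimulated list 2 of 45 were higher and 0 lower (4 and 1 adjusted over the list alone), by a median of 0.09 (camera adjusted p = 0.0117, but adjusted p = 0.524 with an estimated correlation). LT-HSC genes were higher for 2 and lower for 0 of 40 (10 and 1 adjusted over the list alone; camera adjusted p = 4.27e-05, but adjusted p = 0.169 with an estimated correlation). Ribosomal protein genes were lower for 6 of 45 with 0 higher (25 lower adjusted over the list alone; camera adjusted p = 6.33e-17, but adjusted p = 0.218 with an estimated correlation). Also, 21 of the 710 small or ribosomal RNAs tested were lower and 1 higher, beside the shares of these RNAs in VF vehicle libraries 1, 2 and 4 given above. The mitochondrially encoded list had 0 of 15 called, and as many adjusted over the list alone (camera adjusted p = 1.22e-09, but adjusted p = 0.218 with an estimated correlation). Mitochondrial counts made up 1.82% and 0.859% of VF vehicle libraries 1 and 4 and 9.54% and 11.8% of libraries 2 and 3.

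Of 212 genes, 38 were higher and 174 lower in VFDM vehicle. The count was 130, 815 and 63 without VF vehicle libraries 1, 3 and 4, and 71, 79, 72 and 91 without VFDM vehicle libraries 1 to 4. It was 629 with DESeq2, 899 with limma voom, 45 without VF vehicle libraries 1 and 4 and 809 without the libraries with fewer than 20000 detected rows, all from other groups.

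Averaged over the 4 treatments, 525 genes differed between the genotypes, 176 higher and 349 lower in VFDM. Ifi204 (4.32 ± 0.30, adjusted p = 1.75e-10), Ifi211 (3.71 ± 0.27, adjusted p = 9.12e-11) and Slamf1 (0.84 ± 0.11, adjusted p = 5.56e-06) were higher again. Ifi213 of the same cluster, chosen after its values were seen, was called the other way (-3.42 ± 0.91, adjusted p = 0.0487). It stood at 1.38, 1.77 and 4.42 CPM in VFDM IFN libraries 1, 2 and 4 and at 75.3 in the library labelled VFDM IFN 3, against 90.9 ± 12.2 in VF IFN, and at 0 in each VFDM vehicle library, and this call was not recomputed with libraries left out. Cd48 was higher too (0.96 ± 0.24, adjusted p = 0.0248), with 17.9 ± 4.43 CPM in VFDM COMBO, but Cd48 did not pass without VF vehicle libraries 1 and 4 (adjusted p = 0.0717) or without the libraries with fewer than 20000 detected rows (adjusted p = 0.142). Cd244a, a receptor gene of the same chromosome, was lower (-2.20 ± 0.34, adjusted p = 1.39e-04). Nucleic acid sensing genes were higher for 10 of 24 and lower for 0 (12 and 2 adjusted over the list alone; list adjusted p = 1.62e-04). The interferon-stimulated list, which rose in VFDM AZA and not in VF AZA, had 29 of 45 higher and 0 lower (36 higher adjusted over the list alone; list adjusted p = 1.15e-05), Ifi44 by 0.90 ± 0.09 (adjusted p = 1.9e-07). Erythroid markers were higher for 10 of 24 and lower for 0 (15 higher adjusted over the list alone; list adjusted p = 0.00361). This average joins unlike treatments, the mean log2 level of the list in VFDM and VF being 1.37 and 1.62 in vehicle, 3.06 and 3.02 with IFN, 3.33 and 1.25 with AZA and 6.80 and 3.29 with COMBO. In the LT-HSC list 1 were higher and 5 lower of 40 (2 and 8 adjusted over the list alone; camera adjusted p = 0.0428, but adjusted p = 0.523 with an estimated correlation). The mean log2 level of that list was lower in VFDM with COMBO only (4.24 and 5.25), and 6.32 and 6.10 in vehicle, 6.09 and 5.96 with IFN and 6.14 and 6.10 with AZA. Procr was at -1.48 ± 0.31 (adjusted p = 0.00518), Flt3, a cytokine receptor of early progenitors, at -1.61 ± 0.26 (adjusted p = 4.53e-04) and Cd34 at -1.06 ± 0.19 (adjusted p = 0.00209). In the methylation machinery list 2 of 25 were lower and 0 higher (5 and 1 adjusted over the list alone; list adjusted p = 0.0229), the deleted gene Dnmt3a among them. Camera and fry adjusted p ran from 1.7e-04 to 0.169 over the 7 alternatives of this list, so the call did not hold in all of them. The Y-linked and X-inactivation list was higher in VFDM (list adjusted p = 0.00758), with 0 of 4 members past the test over all genes and 1 adjusted over the list alone, and this average includes VFDM COMBO. Without VF vehicle libraries 1 and 4 the count was 318.

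**Figure D5:**
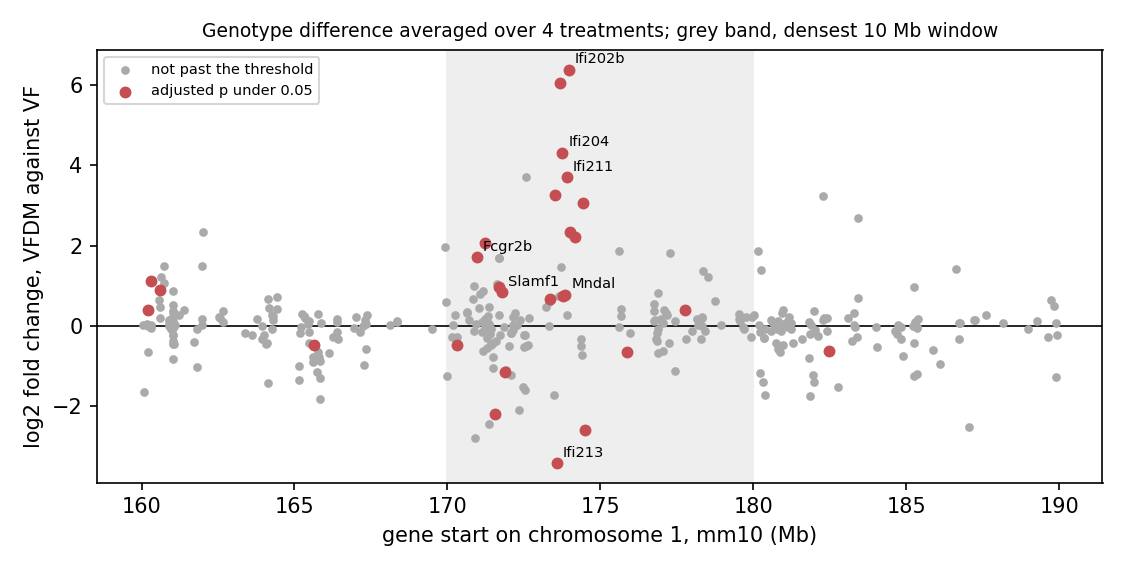
Log2 fold change of VFDM against VF, averaged over 4 treatments, for genes along distal chromosome 1 (mm10, Mb); red points passed the test and the grey band marks the 10 Mb window with most calls. In the band 22 genes passed, 16 higher and 6 lower, and Ifi204 stood at 4.32.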

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

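The tests of explanations in this part, and the comparison of VFDM AZA with VFDM IFN, were chosen after the results were seen, while the differences between the genotypes were planned. Single libraries were compared with the other 3 of their group on 19 measures in 7 groups of 4, and a library was listed when its gap to the nearest other, as a share of the group's range, exceeded Dixon's 95% critical value. This marked 14 of 133 combinations, where chance alone marks about 1 in 20 groups (6.65 here). For Dnmt3a the library labelled VFDM IFN 3 stood at 162 CPM (others 102 to 111) and VFDM vehicle library 4 at 109 CPM (others 119 to 120). For Xist VF IFN library 1 stood at 5180 CPM (others 3340 to 3650) and VFDM vehicle library 4 at 3390 CPM (others 3810 to 3870). Mitochondrial counts made up 10.7% of VFDM vehicle library 3 (others 9.51% to 9.71%), and ribosomal protein genes 2.18% of VF vehicle library 2 (others 1.81% to 1.83%) and 1.9% of the library labelled VFDM IFN 3 (others 1.79% to 1.8%). On the mean log2 level of gene lists, the interferon-stimulated list was at 4.76 in VFDM vehicle library 3 (others 4.62 to 4.64) and 6.53 in VFDM AZA library 2 (others 6.27 to 6.30), the LT-HSC list at 6.31 in VF AZA library 1 (others 6.01 to 6.05), and the megakaryocyte list at 3.86 in VFDM AZA library 3 (others 4.72 to 4.82). T and NK cell markers were at -2.48 in VF vehicle library 1 (others -2.11 to -2.09), 0.30 in VFDM IFN library 4 (others -1.98 to -1.78) and -3.69 in VFDM AZA library 3 (others -2.29 to -2.14).

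The response to azacytidine differed between the genotypes, with 129 genes past the interaction test and 28 of the 45 interferon-stimulated genes higher in it. A swap of libraries in exchange with another group of the series was argued against, since a partner would sit out of place. Here 0 libraries labelled IFN or COMBO had an interferon-stimulated list mean at or below the highest vehicle library. This count does not decide against wrong labels without an exchange. A library labelled VFDM IFN had 162 CPM of Dnmt3a, within the range of the VF IFN libraries (160 to 178 CPM). Among the VF IFN libraries no displaced partner was seen for it. Whether 5-azacytidine released methylation-silenced genes where Dnmt3a is lost cannot be told apart from no release, because 0 germline genes rose in VFDM AZA (edgeR) but only 10 of the 40 listed were tested, and repeat transcripts were not analysed here. Interferon exposure of the animals labelled VFDM AZA stays a candidate explanation. The interferon-stimulated list lay a median of -0.20 from VFDM IFN on the log2 scale, and 0 genes passed between VFDM AZA and VFDM IFN (edgeR). The VFDM non-additivity term (451 genes) would then count interferon with both drugs. The mean log2 level of the neutrophil list was -2.38 in VFDM AZA, with markers at the detection floor, and 2.14 in VFDM IFN (0.85 to 3.76). Among the other groups given interferon it was 3.78 in VFDM COMBO but -1.17 in VF COMBO (-2.67 to 1.34), beside -1.5 in VF vehicle. A low level of this list therefore does not decide against exposure. A biological dependence of the azacytidine response on Dnmt3a stays open beside interferon exposure and wrong labels without an exchange, untested here.

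The response to both drugs differed between the genotypes for 830 genes, 16 LT-HSC genes being lower in VFDM among them. Mature red cells and neutrophils among the sorted cells were argued against as the whole cause. The 4 globin genes, S100a8 and S100a9 took at most 1.88% of the counts of a VFDM COMBO library (haemoglobin 1040, 18500 and 3020 CPM, S100a9 23.8 to 490 CPM and 69, 296 and 141 counts of 4 Y-linked genes in libraries 2, 3 and 4). A fall of the LT-HSC list by a median of 1.53 would need such cells to make up most of the sample. The gate is meant to remove lineage-positive cells, but these transcripts were present after it. Other mature cells, such as lymphocytes, were not covered by these genes. The B cell list had a mean log2 level of -0.5 in VFDM COMBO and -2.1 in VFDM vehicle (camera adjusted p = 0.00583, highest 0.346 over 7 alternatives). T and NK markers were at -1.19 and -2.16 (camera adjusted p = 0.0118, highest 0.427). Loss of transcripts in libraries with few detected genes was not decided. Without the libraries with fewer than 20000 detected rows the list still passed in VFDM COMBO against VFDM vehicle with camera's preset correlation (adjusted p = 6.7e-14, with 6.7e-14 to 8.44e-04 over its 7 alternatives). The VFDM COMBO libraries kept held at most 21262 detected rows and the VFDM vehicle libraries at least 23753, so a gap in detection stayed. The genotype difference of the list was not given in this setting. A response to both drugs that differs between the genotypes cannot be told apart from a changed mix of cells, since the list's adjusted p in the interaction (0.00108 with an estimated correlation) restates the pattern and 8 erythroid markers were higher in the same term. A small admixture of male blood cells, with mature-cell transcripts at up to 1.88% of the counts, and early erythroid progenitors stay open as well. The sort required both Kit and Sca1. Ly6a, which encodes Sca1, rose in VF IFN, VFDM IFN and VFDM AZA, so how well the gate removed such progenitors is uncertain. The erythroid list of 24 genes was written before the data were examined.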

How the results depend on the processing

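RLE size factors, no low-count filter, DESeq2, limma voom with quality weights, a replicate block, fits on the compared groups alone, each library left out in turn, and list tests with an estimated correlation or fry were chosen before the data were examined. Protein-coding rows only, no VF vehicle libraries 1 and 4, no libraries with fewer than 20000 detected rows, and list tests without the library labelled VFDM IFN 3 were added after the data were seen. The 17 planned comparisons were recomputed in the first 3 of these added settings, those with no library removed included, and only list tests in the last. Causes of the changes below were not tested. With RLE size factors the 17 counts stayed within 1.5 times, and 811 of 821 named gene values kept their direction and stayed past the threshold. Without the low-count filter 717 of 821 did, and the counts that moved were the vehicle genotypes (136) and VF non-additivity (11).

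DESeq2 raised 16 of 17 counts by more than 1.5 times and kept 814 of 821 gene values past the threshold: VF IFN 954, VF AZA 843, VF COMBO 2987, VFDM IFN 331, VFDM AZA 418, vehicle genotypes 629, genotype average 881, VF COMBO against IFN 189 and against AZA 1212, VFDM COMBO against IFN 2656 and against AZA 2650, the IFN, AZA and COMBO interactions 33, 381 and 1833, and VF and VFDM non-additivity 237 and 853. limma voom with quality weights kept 554 of 821 gene values and moved 10 counts: VF IFN 1258, VF AZA 23, VF COMBO 283, VFDM IFN 1950, VFDM AZA 796, vehicle genotypes 899, VF COMBO against AZA 101, the IFN and COMBO interactions 5 and 262, and VF non-additivity 0. Under voom Jchain turned from 7.02 to -1.04 in VF COMBO and from 7.91 to -0.40 against AZA.

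Fits on the compared groups alone (16 comparisons, the genotype average using all groups) gave VF AZA 0, VF COMBO 117, VFDM IFN 1092, VFDM AZA 478, vehicle genotypes 130, VF COMBO against AZA 49, VFDM COMBO against AZA 757, the AZA and COMBO interactions 68 and 298, and VF and VFDM non-additivity 0 and 730, with 478 of 751 gene values past the threshold. On protein-coding rows VF AZA had 37, the vehicle genotypes 97, VF COMBO against IFN 1, the AZA interaction 81 and VF non-additivity 0, and 754 of 775 gene values passed. Without VF vehicle libraries 1 and 4 the counts were VF IFN 205, VF AZA 113, VF COMBO 358, vehicle genotypes 45, genotype average 318, the AZA and COMBO interactions 70 and 328, VF COMBO against IFN 4 and VF non-additivity 48, and 616 of 821 gene values passed. Without libraries with fewer than 20000 detected rows VF IFN had 1522, VFDM IFN 631 and the vehicle genotypes 809, groups with no library removed, VF AZA had 3, VF COMBO 228, VFDM COMBO 6062, VF COMBO against IFN 0 and against AZA 45, VFDM COMBO against IFN 3742 and against AZA 2969, the AZA interaction 61, and VF and VFDM non-additivity 2 and 1353, and 580 of 821 gene values passed. In this setting Jchain turned to -4.05 in VF COMBO and -4.13 against AZA, and Cd3g from 9.98 to -1.64.

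The labels give the groups the same replicate numbers but no shared animal or day, so a replicate block was run as an alternative. Libraries with the same number did not deviate together: 0 of 28 pairs of groups had every correlation over 0.1, single correlations ran from -0.12 to 0.17, and a library correlated best with its own number in 29 of 105 cases. With the replicate block VF non-additivity had 2 genes, the other 16 counts stayed within 1.5 times and 726 of 821 gene values stayed past the threshold.

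Leaving out each library in turn gave 273 to 1040 genes for VF IFN, 85 to 942 for VF AZA, 823 to 3007 for VF COMBO, 120 to 227 for VFDM IFN, 112 to 285 for VFDM AZA, 63 to 815 for the vehicle genotypes, 1 to 276 for VF COMBO against IFN and 218 to 1017 against AZA, 1092 to 1451 for VFDM COMBO against IFN and 1039 to 1565 against AZA, 0 to 70, 86 to 269 and 524 to 1124 for the IFN, AZA and COMBO interactions, and 0 to 192 and 297 to 443 for VF and VFDM non-additivity. Of 8410 gene values from these fits 6949 kept their direction and stayed past the threshold, 1459 no longer passed and 2 turned: Cd4 in VF COMBO, with log2 fold changes from -0.22 (without VF COMBO library 1) to 8.32, and Neb in VFDM COMBO against AZA, from -1.13 (without VFDM COMBO library 4) to 6.79.

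Of 106 list calls with camera's preset correlation in the 8 main comparisons, 33 were kept with an estimated correlation, 54 with fry, 102 with RLE size factors, 104 with the replicate block, 102 without the library labelled VFDM IFN 3, 95 without VF vehicle libraries 1 and 4, and 92 without libraries with fewer than 20000 detected rows. List calls of the other comparisons were given an estimated correlation and fry only. Without VF vehicle libraries 1 and 4 the list of mitochondrially encoded transcripts turned from higher to lower (these libraries had mitochondrial shares of 1.82% and 0.859%), with adjusted p = 0.00359 in VF IFN (1e-08 to 0.186 over its 7 alternatives), 5.86e-05 in VF AZA (6.85e-07 to 0.564), 1.62e-04 in VF COMBO (1.25e-04 to 0.626) and 0.118 between the vehicle genotypes (6.94e-10 to 0.218). Totals of 17782394 to 73910928 counts set the floor, and a count of 0 in the smallest library allows up to 0.173 CPM.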

Other observations

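The tests of explanations in this part, the regroupings and the comparisons of azacytidine groups in the next paragraph were chosen after the results were seen. Transgene levels, singled out after their values were seen, differed between the genotypes on average. Averaged over the 4 treatments, the row CreERT2, which encodes the inducible recombinase, was higher in VFDM by 0.94 ± 0.10 (edgeR, adjusted p = 1.9e-07) and the reporter row pEGFP by 0.93 ± 0.13 (adjusted p = 8.79e-05). In vehicle CreERT2 was at 224 ± 19.5 CPM in VFDM and 133 ± 39.4 CPM in VF, and pEGFP at 387 ± 23.7 and 218 ± 88.6 CPM. Vehicle libraries did not overlap (CreERT2 198 to 244 CPM in VFDM and 86.8 to 173 in VF, pEGFP 355 to 412 and 110 to 325). Over all treatments they did: the library labelled VFDM IFN 3 held 113 and 251 CPM, the lowest VFDM COMBO library 153 CPM of CreERT2 and the lowest VFDM AZA library 301 CPM of pEGFP. In VFDM COMBO libraries 2, 3 and 4 pEGFP was at 389, 1030 and 514 CPM. Human JAK2 exons 3 to 12 were at 77.8 ± 42.9 CPM in VF vehicle, 112 ± 9 in VF IFN, 107 ± 10.7 in VF AZA and 105 ± 16.2 in VF COMBO, and at 79.8 ± 9.54, 87.5 ± 14.8, 108 ± 12 and 81.8 ± 19.9 CPM in the VFDM groups in the same order. Exons 13 to 25 of that gene were at 62 ± 40.2, 65.7 ± 8.49, 79.7 ± 19.9 and 87.8 ± 50.9 CPM in the VF and 93.4 ± 8.31, 76.6 ± 4.22, 101 ± 26 and 64.7 ± 15.4 CPM in the VFDM groups. The row of these exons inverted made up 9.68%, 18.3%, 13.9% and 13.5% of their counts in the VF and 4.82%, 8.1%, 7.1% and 7.45% in the VFDM groups (group means of the libraries). The shares were not tested, and none of these 3 rows passed the edgeR test between the genotypes in vehicle or on average.

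Azacytidine groups were also set against each other and against interferon. VFDM AZA against VF AZA had 164 genes past the edgeR test, and 37 of 45 interferon-stimulated genes were higher and 0 lower (43 higher adjusted over the list alone; list adjusted p = 3.8e-09), with Ifi44 at 160 ± 24.7 against 22.7 ± 5.93 CPM (2.82 ± 0.19, adjusted p = 1.92e-11) and Usp18 at 55.4 ± 9.28 against 7.04 ± 3.05 CPM (2.97 ± 0.26, adjusted p = 2.47e-09). Erythroid markers were higher for 9 of 24 and lower for 0 (16 and 1 adjusted over the list alone; list adjusted p = 0.0127), Car1 standing at 41 ± 29.4 against 0.33 ± 0.571 CPM. VF AZA against VF IFN had 153 genes, 37 of the 45 interferon-stimulated genes being lower and 0 higher (43 lower adjusted over the list alone; list adjusted p = 4.3e-09), while Sema4b, a semaphorin, was higher in VF AZA (81.4 ± 16.5 against 42.7 ± 2.97 CPM; log2 fold change 0.93 ± 0.17, adjusted p = 0.00114). Megakaryocyte markers were lower for 5 of 26 and higher for 0 (11 lower adjusted over the list alone; list adjusted p = 0.0254). These added comparisons were not recomputed with libraries left out.

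Genes that differ between the genotypes crowded on distal chromosome 1. Between 170 and 180 Mb, 22 of 147 tested genes passed in the average over treatments, 16 higher and 6 lower, where the next densest window of 10 Mb held 13 and the densest window of 1000 random draws of as many genes held at most 18 (permutation p = 0.001, the smallest these draws can give). The interferon response, to which many genes of the region belong, was argued against as the whole cause, since 9 genes of the same window passed in vehicle libraries (next window 8, 3 of 1000 draws as large, highest draw 10, permutation p = 0.004), where the interferon-stimulated list had a median of 0.09. The draws placed genes independently of each other. Called genes of the window include neighbouring near copies such as Ifi204, Ifi211 and Mndal. Neighbours that move together or share reads make both permutation p-values too small, so these do not decide whether the whole stretch is crowded. A stretch of another strain's chromosome carried with one genotype may explain the 22 genes, but no sequence variants were analysed here, and near copies in the Ifi200 family leave read assignment uncertain. The library labelled VFDM IFN 3, with the Dnmt3a level of VF libraries, also had 12.5 CPM of Ifi204, near the VF IFN libraries (6.39 to 13.8).

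Other groupings of the same libraries were counted for each number of called genes, the real one included. At 1 of the 35 regroupings, the real grouping alone reached the count for VF IFN (538 genes, highest other 74) and VF COMBO (1838, highest other 920). The same held for VFDM IFN (214, highest other 0), VFDM AZA (205, highest other 0) and VFDM COMBO (3551, highest other 303). It also held for the vehicle genotypes (212, highest other 43), VFDM COMBO against VFDM IFN (1748, highest other 124) and against VFDM AZA (1733, highest other 782). This is the smallest share possible and was not corrected over the 17 comparisons, so chance was not excluded. Regroupings mix libraries of both groups, so a real effect widens the spread within groups and lowers their counts. At 1 of 30 regroupings, again the smallest share possible, the real grouping alone reached the count of the genotype average (525, highest other 58). The same share was found for the AZA interaction (129, highest other 0), the COMBO interaction (830, highest other 239) and VFDM non-additivity (451, highest other 0). Regrouping for interaction and non-additivity terms mixed genotypes or treatments, so main effects entered the spread within groups. Low counts there cannot decide whether these terms arose by chance. The share was also 1 of the 35 regroupings for VF AZA (265, highest other 250) and VF COMBO against VF IFN (2, highest other 1). The margins were small, and the counts were 0 for VF AZA with the compared groups alone and 1 for VF COMBO against VF IFN without any of the 4 VF IFN libraries. For VF COMBO against VF AZA 4 of the 35 regroupings gave as many genes (411, highest other 560). For VF non-additivity 3 of 30 did (19, highest other 109). Both counts thus lay within the range of the regroupings. For the IFN interaction the edgeR count was 0, so all 30 regroupings were as large by construction (highest other 1) and say nothing about chance. The 109 genes of VF non-additivity came from the highest regrouping, and why it exceeded the real count was not tested. In the VF treatments against vehicle the highest regrouping exchanged VF vehicle library 3 and 1 treated library, and so kept much of the real contrast.

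Detection was lower with azacytidine: 8 of the 15 libraries labelled AZA or COMBO and 0 of the 16 others had fewer than 20000 detected rows, a limit chosen after the data were seen (Fisher exact p = 8.16e-04). Detected rows depend on the total, and group mean totals were 25000000 to 33200000 counts with azacytidine and 35900000 to 50000000 without, so depth was not separated from the drug. The Y-linked and X-inactivation list rose in VFDM COMBO, 2 of 4 members up and 0 down (2 up adjusted over the list alone; list adjusted p = 0.0332), with 69, 296 and 141 counts of 4 Y-linked genes in libraries 2, 3 and 4, which held haemoglobin at 1040, 18500 and 3020 CPM.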
